A study of Mus musculus with 10 samples.

How the data were processed

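RNA was measured in neurites of embryonic day 16.5 mouse cortical neurons grown for 8 days on membranes with 3 µm pores. Per the labels' protocols, all cultures received an adeno-associated virus carrying Cre, injured neurites were scraped off the underside on day 7 and lysed 24 hours later, and cell bodies were wiped off the upper side before lysis. Per the labels' protocols, 1 ng of RNA was reverse transcribed from poly(A) tails by Smart-seq2 with 14 cycles of PCR, and 500 pg of cDNA was tagmented and amplified with 11 cycles. Such libraries are not stranded. The wild-type neurons were of the C57BL/6 strain, and the others carried floxed Cpeb1 on the same background. What the shared replicate numbers mean and which Cpeb1 exons are deleted are not given in the sources used here.

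The submitters' processing notes name STAR 2.4.2a for alignment and RSEM 1.2.21 for quantification. The values deposited for 45195 Ensembl gene IDs in 10 libraries were taken as FPKM from the authors, each library divided by its TMM normalization factor. The notes do not state this, and it rests on the values. In each library at least 99.9956% of values lay within 0.001 of a whole multiple of 0.01 times a factor. That factor times the TMM factor, computed anew from the undivided values rounded to whole numbers, deviated from 1 by at most 2.72e-08. The column totals were not multiplied into the factor. Depth was estimated per library from genes with 1 annotated transcript of 300 to 2500 nt. Their undivided values times effective length should, for FPKM, be whole multiples of a step set by the depth, and the strongest such step was taken over a range of fragment lengths. It ranged from 20.9 to 27.3 in units of 1e6 fragments. In simulated columns with a known depth this estimate was within 0.301%. Counts were not used here, so no counting intervals are given. Of the gene IDs 44548 matched GENCODE release M21 (mm10), which gave names, coordinates, transcript lengths and 3' untranslated regions, and 647 did not. No gene of the mitochondrial chromosome was among the values.

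Groups were taken from the labels. The test was limma 3.58.1 (R 4.3.3) on log2(value + 1) with eBayes and a mean-variance trend, 4 group means in 1 fit of all 10 libraries, over the 15712 genes with a value of at least 1 in at least 2 libraries. Of these 13214 were protein coding, 632 pseudogenes and 1057 had a near-identical copy. P-values were adjusted by Benjamini and Hochberg within a comparison with a threshold of 0.05, and every adjusted p of a gene in the text is from limma. The residual degrees of freedom were 6 and the prior degrees of freedom 6.80. The comparisons were injury in each genotype, genotype in naive and in injured neurites, and the interaction, the injury effect in the knockout minus that in wild type. Log2 fold changes are differences of group means of log2(value + 1), with SE from the fit. Group means and SDs are of the deposited values.

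A set of 33 gene lists, written before the values were seen, was tested with camera at a preset correlation of 0.01, where at least 5 members were measured, which left 32. Adjusted p-values are over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. The lists described in the report were picked after the list results were seen. Genes with a cytoplasmic polyadenylation element (TTTTAT or TTTTAAT in the longest annotated 3' untranslated region) were tested the same way, with p-values adjusted over the 5 comparisons, and also adjusted for length and GC content of that region. The responses of both genotypes were compared by the number of called genes with the same sign and by fry on the called genes, where at least 5 were called in a direction, with p-values adjusted over the 3 sets.

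The rule for named genes was written before the values were seen. It took Cpeb1 to Cpeb4 in every comparison. In each pairwise comparison it took the 6 largest rises and 6 largest falls among genes that passed, with mean expression at or above the median and no overlap between the groups, filled up by the smallest p where fewer passed. It took the 3 smallest p in each direction of the interaction with mean expression at or above the median, and up to 4 members with the smallest p of each list described. Unnamed gene models and pseudogenes were passed over, and others named in the text are said to have been chosen after their values were seen.

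Near-identical copies were found with blastn 2.17.0 (megablast) between 1 transcript per tested gene, on the same strand, at 95% identity over at least 150 nt and 50% of the shorter transcript. Copies in genes that were not tested are not seen by this search. The transcript choice behind it was changed to prefer protein-coding transcripts after the genotype calls were seen. Exons of named genes were also compared with those of all other tested genes for overlap on either strand. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

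The limma test was tested on simulated data with 15712 genes, each with its real mean and residual SD and normal noise, and 50 changed by each of log2 values 1, 2, 3 and 4. The changed genes were drawn from those with mean expression at or above the median, so the recovered shares hold for such genes only. For injury in wild type 20%, 72%, 86% and 98% of those were recovered, for injury in the knockout 6%, 48%, 68% and 88%, for genotype in naive neurites 10%, 64%, 82% and 98%, for genotype in injured neurites 8%, 62%, 88% and 86%, and for the interaction 4%, 18%, 64% and 54%. Of the genes called, 1.87% to 5.93% were unchanged ones. The simulated noise was independent between genes and had the same SD in every library, as the test assumes. Real libraries varied unequally, with array weights, lower for libraries that vary more, of 0.405 to 1.50. The simulated shares may therefore not hold for the real data. The camera test ranked a list shifted by 0.5 ahead of all others in simulated data. The fry tests, the adjustment for length and GC content and the copy search were not simulated.

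Alternatives were quantile normalization, median-ratio scaling, no filter beyond a value above 0, a minimum value of 5, pseudocounts of 0.1 and 5, limma without trend, limma with array weights, a fit of only the groups compared, a replicate block and leaving out each library in turn. For the lists they were an estimated correlation, fry with the replicate block and leaving out each library, and for the motif the shorter motif alone and its position within 100 nt of the end. For the genes a pair of alternatives was added after seeing the data, the normalization factor multiplied by the column total, and protein-coding genes without a copy only. Camera on the lists with quantile normalization, median-ratio scaling and the multiplied factor was also added after seeing the data. A check of whether replicate numbers pair libraries correlated the deviations from the group mean, across genes, between libraries that share a number. The 647 unmatched IDs were tested where they met the filter and were not named.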

Results

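RNA was measured from neurites, the axons and dendrites that cultured mouse cortical neurons send through the pores of a membrane while their cell bodies stay on top. The neurons came from wild-type embryos or from embryos with both copies of Cpeb1 flanked by loxP sites, and neurons of both genotypes received a virus carrying Cre recombinase, which deletes the flanked sequence. Cpeb1 is an RNA-binding protein that acts on mRNAs through a motif in their 3' untranslated region. In each genotype neurites were either left alone (naive) or scraped off the underside of the membrane on day 7 and allowed to regrow for 24 hours (injured). The 10 libraries comprised 3 wild-type naive, 3 wild-type injured, 2 knockout naive and 2 knockout injured, and the labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples.

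The depth, estimated from regular steps in the deposited values and in units of 1e6 fragments, was 24.7, 24.3 and 24.7 in the wild-type naive libraries and 21.9, 22.5 and 20.99 in the wild-type injured libraries. It was 24.1 and 20.9 in the knockout naive libraries and 25.9 and 27.3 in the knockout injured libraries. Genes with a value of at least 1 numbered 12920, 13143 and 13036 in wild-type naive, 12611, 13101 and 12231 in wild-type injured, 13128 and 13108 in knockout naive, and 12495 and 12747 in knockout injured libraries. Wild-type injured replicate 3 had the fewest detected genes and the lowest mean correlation with the other libraries, 0.839. Nuclear genes with near-identical copies of mitochondrial sequence held 7.81% ± 0.962 (SD, n = 3) of the total in wild-type naive and 4.74% ± 0.131 (SD, n = 3) in wild-type injured libraries, and 8.94% ± 1.02 (SD, n = 2) and 4.92% ± 0.407 (SD, n = 2) in knockout naive and injured libraries.

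Cpeb1 (ENSMUSG00000025586, chromosome 7, 81347026 to 81455465, mm10) was listed above 0 in every library. Its deposited value was 7.16, 5.96 and 5.86 in the libraries labelled wild-type naive and 1.65, 13.8 and 22.6 in those labelled wild-type injured. It was 5.97 and 0.356 in the libraries labelled knockout naive and 1.14 and 3.15 in those labelled knockout injured. The library labelled knockout naive replicate 1 therefore lay within the wild-type naive range, so the gene-level value went against that label. The value of wild-type injured replicate 1 likewise lay within the knockout injured range. Rps13-ps2 and Gm37750, given below, were listed at 0 in every knockout library, knockout naive replicate 1 included, and above 0 in every wild-type library. They are among the calls made with these labels. Their values went with the label and do not show whether Cpeb1 was deleted. By limma the knockout minus wild-type difference was -1.25 ± 0.91 (log2 fold change ± SE, n = 2 and 3) in naive neurites (adjusted p = 1) and -1.71 ± 0.91 in injured neurites (adjusted p = 0.549). Over the alternatives, leaving out a library included, it ranged from -2.43 to -0.067 in naive and from -2.65 to -1.07 in injured neurites. The labels do not give the deleted exons, and a gene-level value does not show whether reads came from them. All directions between genotypes given here follow the labels.

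**Figure D1:**
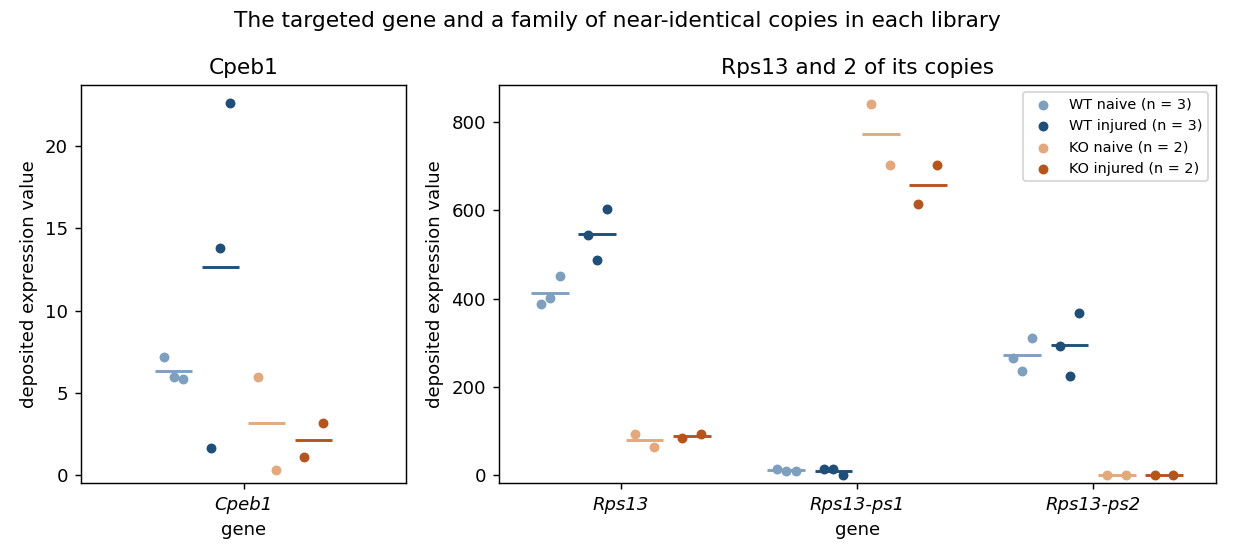
Deposited values (FPKM-like, each panel with its own axis) of Cpeb1, Rps13, Rps13-ps1 and Rps13-ps2 in each of the 10 libraries by group, where each point is 1 library and each line a group mean. Cpeb1 in knockout naive replicate 1, 5.97, lies among the wild-type naive values of 5.86 to 7.16.

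Injury of wild-type neurites asked which transcripts differ in neurites that regrew for 24 hours after scraping. Naive neurites had been left to grow until day 8. Injury and the age of the neurites therefore cannot be told apart in either genotype. Activity-induced transcription factors were among the genes that rose. Fos, a subunit of the AP-1 transcription factor, rose from 2.56 ± 1.61 to 415 ± 129 (mean ± SD, n = 3 and 3), a log2 fold change of 6.91 ± 0.47 (SE; limma adjusted p = 1.68e-05). The orphan nuclear receptor gene Nr4a1 rose from 4.002 ± 0.227 to 263 ± 72.2 (5.68 ± 0.38, limma adjusted p = 1.68e-05), and the AP-1 gene Junb and the stress-response gene Gadd45g rose by 5.65 ± 0.45 and 5.10 ± 0.43 (limma adjusted p = 7.48e-05 and 0.000123). Npas4, an activity-dependent transcription factor of neurons, rose by 5.002 ± 0.54 (limma adjusted p = 0.00101). Of 30 measured immediate early genes 14 rose, none fell, and 23 rose and 1 fell when adjusted over the list alone. Junb, Jun and Dlx1 share 7.52%, 7.28% and 6.21% of their exon bases with overlapping genes, which reads of an unstranded library cannot separate. The list's median was 2.46, and its camera adjusted p was 7.16e-32, with adjusted p = 0.0892 with an estimated correlation.

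Transcripts of inhibitory interneurons were lower after injury. Sst, the neuropeptide somatostatin, fell from 298 ± 121 to 32.9 ± 5.52 (-3.08 ± 0.31, limma adjusted p = 0.000477, n = 3 and 3). Gad1, an enzyme that makes the transmitter GABA, fell from 76.1 ± 2.96 to 10.3 ± 5.87 (-2.90 ± 0.38, limma adjusted p = 0.00396). Dlx1 and Dlx5, transcription factors of the interneuron lineage, changed by -2.97 ± 0.48 and -3.14 ± 0.57 (limma adjusted p = 0.0141 and 0.0242). Over the alternatives these values ranged from -3.55 to -1.95 and from -4.95 to -1.57. Of 16 measured interneuron markers 5 fell and 9 fell when adjusted over the list alone, and all 16 had a log2 fold change of 0 or below. Their median was -1.74, with a camera adjusted p of 8.51e-14 and adjusted p = 0.0623 with an estimated correlation. The list of projection neuron markers had a median of -0.46 (camera adjusted p = 0.0347, and adjusted p = 0.341 with an estimated correlation), and none of its 19 measured members passed the test over all genes, 1 rising when adjusted over the list alone. Among them Neurod2 had a log2 fold change of 1.03 ± 0.25 (limma adjusted p = 0.077) and Bcl11b one of -1.77 ± 0.65 (limma adjusted p = 0.254). The neuropeptide gene Npy fell by 3.45 ± 0.72 on the log2 scale (limma adjusted p = 0.0435). Penk, which encodes enkephalin precursors, was 26.3, 23.8 and 15.5 in naive libraries and listed at 0 in all 3 injured libraries (limma adjusted p = 0.000437). Syndig1, a synaptic membrane protein gene, changed by -3.72 ± 0.61 (limma adjusted p = 0.0141).

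Regeneration-associated genes included members in both directions, with 6 of 35 rising and 1 falling, and 13 rising and 6 falling when adjusted over the list alone (median 0.81, camera adjusted p = 0.0208, and adjusted p = 0.15 with an estimated correlation). The member that fell was Npy, also an interneuron marker. Jun, which is needed for regeneration in other axons, rose from 13.2 ± 2.12 to 138 ± 39.3 (3.26 ± 0.33, limma adjusted p = 0.000477, n = 3 and 3). Atf3, another transcription factor of that response, and Stmn4, a microtubule regulator, rose by 3.66 ± 0.65 and 0.84 ± 0.16 (limma adjusted p = 0.0225 and 0.0279). The Atf3 value ranged from 2.05 to 5.93 over the alternatives, the latter with a pseudocount of 0.1. Heat shock and proteostasis genes had a median of 0.43 (camera adjusted p = 4.18e-07, and adjusted p = 0.0892 with an estimated correlation). Of 27 measured 2 rose, while 12 rose and 1 fell when adjusted over the list alone. Those that rose, Hspa1a (3.11 ± 0.65, limma adjusted p = 0.0432) and Hsp90aa1 (0.65 ± 0.14, limma adjusted p = 0.0478), each have a near-identical copy in the genome, so the assignment of their reads is uncertain. Presynaptic and vesicle genes had a median of -0.55 (camera adjusted p = 6.15e-07, and adjusted p = 0.15 with an estimated correlation). None of their 30 measured members passed the test over all genes and 10 fell when adjusted over the list alone. Cplx1, a regulator of vesicle fusion, had a value of -1.19 ± 0.26 (limma adjusted p = 0.0514).

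Astrocyte and radial glia markers were higher in the injured wild-type neurites. Astrocyte markers had a median of 0.95 (camera adjusted p = 3.7e-08, and adjusted p = 0.194 with an estimated correlation), with 1 of 18 measured members rising and 4 when adjusted over the list alone. That member, Sox9, a transcription factor of glia and their progenitors, rose from 12.4 ± 1.38 to 49.0 ± 13.4 (1.87 ± 0.30, limma adjusted p = 0.0141, n = 3 and 3). Radial glia and progenitor markers had a median of 0.92 (camera adjusted p = 2.24e-05, and adjusted p = 0.194 with an estimated correlation), with 1 of 16 measured rising and 5 when adjusted over the list alone. It was Vim, an intermediate filament gene of immature glia, which rose by 1.88 ± 0.39 (limma adjusted p = 0.0435). In the injured libraries the astrocyte median relative to wild-type naive was 0.64, 0.54 and 1.48, highest in wild-type injured replicate 3, the library that stood apart. Cytosolic ribosomal protein genes were shifted together by a small amount, with a median of 0.40 and 77 of 79 above 0 (camera adjusted p = 4.17e-17, and adjusted p = 0.341 with an estimated correlation). Only Rpl12 rose, over all genes and when adjusted over the list alone (1.33 ± 0.26, limma adjusted p = 0.0353). It has a near-identical copy, and a small RNA gene, Snora65, lies inside its exons, so its value is uncertain. The ribosomal median was 0.30, 0.13 and 0.76 in the 3 injured libraries, again highest in replicate 3. That library also had the largest share of CT010467.1, annotated as ribosomal RNA, and AY036118, which lies within it, 28.2% of the total against 19.9% and 23.3% in replicates 1 and 2. Without that library the ribosomal and radial glia medians were 0.23 and 0.60, and with quantile normalization the ribosomal median was 0.23.

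Nuclear-retained transcripts, which would mark cell bodies, had a median of -0.17 (camera adjusted p = 0.868, and adjusted p = 0.948 with an estimated correlation). It was 0.018 and -0.28 without wild-type injured replicate 1 or 2. Of the 12 measured 1 rose, and 1 rose and 1 fell when adjusted over the list alone. The nuclear long noncoding RNA Malat1 rose from 2633 ± 792 to 5988 ± 579 (1.23 ± 0.26, limma adjusted p = 0.0455, n = 3 and 3), and it shares 6.49% of its exon bases with the overlapping gene Gm37376. Rn7sk, a small nuclear RNA that holds back transcription elongation, rose from 17.4 ± 8.78 to 444 ± 166 (4.67 ± 0.55, limma adjusted p = 0.00176). The libraries were primed from poly(A) tails, so how reads of this small nuclear RNA arose is uncertain. The antioxidant enzyme gene Hmox1 rose by 2.02 ± 0.39 (limma adjusted p = 0.0343).

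In this comparison limma called 149 genes, 110 higher and 39 lower, and 2184 had an unadjusted p under 0.05. The share higher was 73.8%, against 61.0% with quantile normalization, 65.2% with median-ratio scaling and 59.8% with the normalization factor multiplied by the column total. The number called was 25 with no filter on low values, 12 higher and 13 lower, 77 without a mean-variance trend and 17 when the knockout libraries were not used. It was 35, 44 and 58 without wild-type naive replicate 1, 2 or 3, 64, 311 and 84 without wild-type injured replicate 1, 2 or 3, and 97 and 99 without knockout naive replicate 1 or 2.

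Fos, Nr4a1, Junb, Gadd45g, Npas4, Jun, Rn7sk, Penk, Sst and Gad1 passed with any 1 library left out. Syndig1, Dlx1 and Sox9 did not pass without wild-type naive replicate 1 (limma adjusted p = 0.0964, 0.0964 and 0.0733) or replicate 2 (limma adjusted p = 0.0793, 0.0772 and 0.0723). Atf3 did not pass without wild-type naive replicate 2 or 3 or wild-type injured replicate 3 (limma adjusted p = 0.116, 0.102 and 0.0676). Stmn4 did not pass without any 1 wild-type naive library or wild-type injured replicate 1 (limma adjusted p = 0.0894 to 0.137), nor did Dlx5 without those or wild-type injured replicate 3 (limma adjusted p = 0.0552 to 0.137). Npy and Vim were lost without any wild-type naive library, wild-type injured replicate 1 or 3, or either knockout naive library (limma adjusted p = 0.0618 to 0.187 and 0.0529 to 0.202). Hmox1 was lost without the same libraries except wild-type naive replicate 2, and also without knockout injured replicate 2 (limma adjusted p = 0.0516 to 0.149). Rpl12 was lost without any wild-type naive library, wild-type injured replicate 1 or 3, or either knockout injured library (limma adjusted p = 0.051 to 0.14). Malat1 was lost without any wild-type or knockout naive library or any wild-type injured library (limma adjusted p = 0.0562 to 0.191), and Hspa1a and Hsp90aa1 were lost without any library but wild-type injured replicate 2 (limma adjusted p = 0.0502 to 0.185 and 0.0604 to 0.199). Cplx1 passed without wild-type injured replicate 2 (limma adjusted p = 0.0469) and not without any other library, and it passed with quantile normalization, median-ratio scaling, a minimum value of 5, a pseudocount of 5, the factor multiplied by the column total, and among protein-coding genes without a copy (limma adjusted p = 0.0382 to 0.0486). The camera call for regeneration-associated genes ended without wild-type injured replicate 2 or 3 (adjusted p = 0.0799 and 0.053), and that for projection neuron markers ended without wild-type naive replicate 1 or 2 or wild-type injured replicate 3 (adjusted p = 0.0537, 0.0784 and 0.364). Without wild-type injured replicate 3 the medians of these lists were 0.51 and -0.24.

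Other settings also ended calls in this comparison. Fos, Nr4a1, Junb, Gadd45g, Npas4, Jun, Penk and Sst passed in all 12 settings other than leaving out a library. Rn7sk was lost with no filter (limma adjusted p = 0.0611). Gad1, Syndig1, Dlx1 and Sox9 were lost with no filter (limma adjusted p = 0.0552, 0.092, 0.0752 and 0.0506) and in a fit of only the groups compared (limma adjusted p = 0.0658, 0.124, 0.135 and 0.0883). The other calls named here were lost in more settings (out of 11 for genes that have a copy or do not code for protein, which the restricted set leaves out), Dlx5 in 3 of 12 (limma adjusted p = 0.0595 to 0.107), Npy in 4 of 12 (limma adjusted p = 0.0795 to 0.238), Atf3 in 4 of 12 (limma adjusted p = 0.0669 to 0.149), Vim in 5 of 12 (limma adjusted p = 0.0656 to 0.227), Stmn4 in 5 of 12 (limma adjusted p = 0.0701 to 0.253), Hmox1 in 5 of 12 (limma adjusted p = 0.0588 to 0.18), Rpl12 in 5 of 11 (limma adjusted p = 0.0556 to 0.127), Hspa1a in 6 of 11 (limma adjusted p = 0.0534 to 0.172), Hsp90aa1 in 7 of 11 (limma adjusted p = 0.0568 to 0.351) and Malat1 in 8 of 11 (limma adjusted p = 0.0566 to 0.251).

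**Figure D2:**
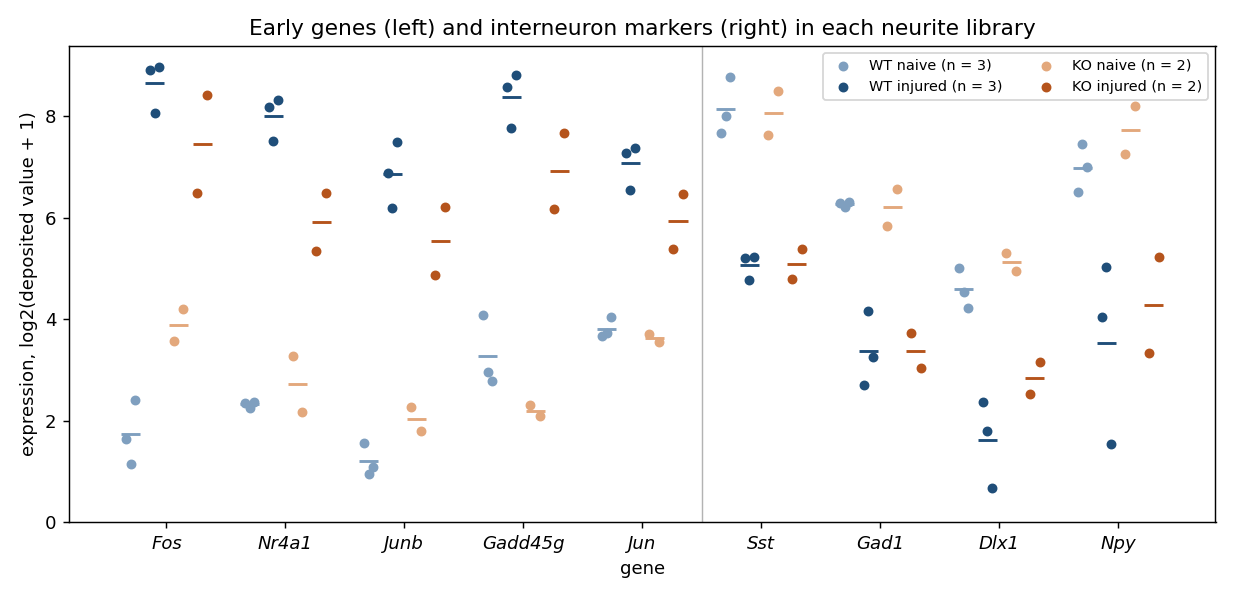
Log2(deposited value + 1) of 5 genes that rose and 4 that fell after injury in wild-type neurites, by group, where each point is 1 library and each line a group mean. Mean Fos went from 2.56 to 415 and mean Sst from 298 to 32.9 in deposited units between wild-type naive and injured libraries.

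Injury of knockout neurites asked for the same response in neurites labelled as lacking Cpeb1. Gadd45g rose from 3.60 ± 0.479 to 137 ± 93.3 (4.72 ± 0.53, limma adjusted p = 0.0123, n = 2 and 2), Junb by 3.50 ± 0.55 (limma adjusted p = 0.0475) and Nr4a1 by 3.19 ± 0.46 (limma adjusted p = 0.0322). Fos had a value of 3.56 ± 0.58 and Jun one of 2.30 ± 0.40 (limma adjusted p = 0.0551 and 0.0874). The immediate early list had a median of 1.06 (camera adjusted p = 8.36e-18, and adjusted p = 0.197 with an estimated correlation). Of its 30 genes 3 rose, and 12 when adjusted over the list alone. Its median relative to wild-type naive was 0.21 and -0.28 in the knockout naive libraries and 0.42 and 1.44 in the knockout injured libraries. Without knockout injured replicate 2 the list's median was 0.61.

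Sst fell from 278 ± 113 to 33.9 ± 10.02 in knockout neurites (-2.97 ± 0.38, limma adjusted p = 0.0237, n = 2 and 2), and Gad1 had a value of -2.82 ± 0.46 (limma adjusted p = 0.0559). Interneuron markers had a median of -1.96, and none of the 16 was above 0 (camera adjusted p = 9.55e-14, and adjusted p = 0.0608 with an estimated correlation). Of them 1 fell, and 9 when adjusted over the list alone. Pcp4, a calmodulin-binding peptide found in neurons, fell from 250 ± 55.3 to 54.9 ± 13.5 (-2.17 ± 0.33, limma adjusted p = 0.0369). It is a member of the list of dendritic mRNAs, which had a median of -0.46 over 27 measured genes, 1 of which fell and 3 when adjusted over the list alone (camera adjusted p = 0.000463, and adjusted p = 0.197 with an estimated correlation). Its members Camk2a, a synaptic kinase, and Map2, a dendritic microtubule protein, had values of -1.71 ± 0.38 and -0.99 ± 0.23 (limma adjusted p = 0.252 and 0.309).

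Nuclear-encoded oxidative phosphorylation genes had a median of -0.30 in injured knockout neurites (camera adjusted p = 5.12e-11, and adjusted p = 0.502 with an estimated correlation), with none of 76 measured passing the test over all genes or adjusted over the list alone. Ndufa4, a respiratory chain subunit, had a value of -0.68 ± 0.19 (limma adjusted p = 0.483, n = 2 and 2). Microglia and macrophage markers had a median of -0.97 (camera adjusted p = 0.00511, and adjusted p = 0.197 with an estimated correlation), and none of 13 measured passed either test. The camera call for microglia ended without knockout injured replicate 1 (median -0.58, adjusted p = 0.193), and the median was -1.82 without knockout naive replicate 2. The oxidative phosphorylation median was -0.18 without knockout naive replicate 1 and -0.17 with quantile normalization. Relative to wild-type naive the microglia median was 1.93 and 0.97 in the knockout naive libraries and 0 and 0.06 in the knockout injured libraries.

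With 2 libraries per group limma called 9 genes, 4 higher and 5 lower, and 900 had an unadjusted p under 0.05. Beside Gadd45g, Junb, Nr4a1, Sst and Pcp4, the unnamed models Gm22767 (higher), Gm28661, Gm10925 and Gm11410 (lower) were called, which were chosen for mention after their values were seen. The number called was 33 (14 higher and 19 lower) with no filter, 20 (6 higher and 14 lower) with array weights, 4 (3 higher and 1 lower) with quantile normalization, 14 with the factor multiplied by the column total, and 1 without a trend or with a pseudocount of 0.1. It was 2, 1 and 2 without wild-type naive replicate 1, 2 or 3, 0 and 20 (5 higher and 15 lower) without wild-type injured replicate 1 or 3, and 0 without knockout naive replicate 1 or 2 or knockout injured replicate 2. Gadd45g was lost without wild-type injured replicate 1, either knockout naive library or knockout injured replicate 2 (limma adjusted p = 0.0593 to 0.268). Sst was lost without wild-type naive replicate 2, wild-type injured replicate 1 or any knockout library (limma adjusted p = 0.0593 to 0.38). Nr4a1 was lost without any wild-type naive library, wild-type injured replicate 1, either knockout naive library or knockout injured replicate 2 (limma adjusted p = 0.061 to 0.52). Junb and Pcp4 were lost without any library but wild-type injured replicate 3 (limma adjusted p = 0.0578 to 0.717 and 0.0548 to 0.74). Fos passed without wild-type injured replicate 3 or knockout injured replicate 1 (limma adjusted p = 0.0452 and 0.031), and Gad1 without wild-type injured replicate 2 or 3 (limma adjusted p = 0.0496 and 0.0392). Both also passed with a minimum value of 5, array weights, a pseudocount of 5 and among protein-coding genes without a copy, Fos also with median-ratio scaling, the replicate block and the multiplied factor, and Jun with median-ratio scaling, array weights and the multiplied factor (limma adjusted p = 0.0168 to 0.0419 for Fos, 0.0146 to 0.0481 for Gad1 and 0.0233 to 0.0497 for Jun). Calls were also lost in other settings, Gadd45g without a trend and in a fit of only the groups compared (limma adjusted p = 0.173 and 0.45), Sst in 4 of 12 (limma adjusted p = 0.0504 to 0.45), Nr4a1 in 5 of 12 (limma adjusted p = 0.0713 to 0.497), Pcp4 in 6 of 12 (limma adjusted p = 0.0738 to 0.45) and Junb in 7 of 12 (limma adjusted p = 0.0777 to 0.451).

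Set side by side, the injury responses of both genotypes shared a direction for most wild-type calls. Of the 149 genes called in wild-type neurites, 117 (78.5%) had the same sign in knockout neurites, against 53.3% of all tested genes. Of the 39 that fell 31 were below 0 in the knockout (limma's fry, adjusted p = 0.000132), and of the 110 that rose 86 were above 0, a set that did not pass (fry adjusted p = 0.0504). That higher set passed with quantile normalization, median-ratio scaling and no filter (fry adjusted p = 0.013, 0.0208 and 0.00131), and also with 1 library left out, for every library except knockout naive replicate 2 and knockout injured replicate 2 (fry adjusted p = 0.00579 to 0.0435). The 6 genes called in both were Nr4a1, Junb, Gadd45g, Sst, Pcp4 and Gm28661. The log2 fold changes of all genes correlated weakly (Pearson r 0.178, Spearman rho 0.143, across genes, which are not independent replicates), and these contrasts share no library.

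**Figure D3:**
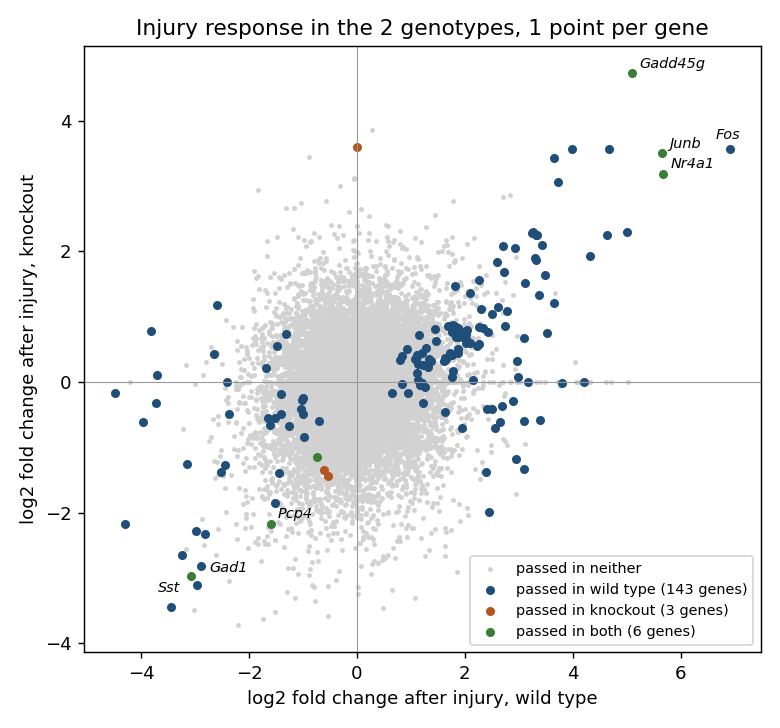
Log2 fold change after injury in wild-type neurites (horizontal axis) against that in knockout neurites (vertical axis), where each point is a tested gene and colours mark the 143 called only in wild type, the 3 called only in the knockout and the 6 called in both. Passing in 1 genotype does not show a difference, since no gene passed the interaction test.

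The naive comparison of genotypes asked how neurites differ before injury when Cpeb1 has been targeted. Most genes that passed were pseudogenes or members of families of near-identical copies, 21 of 23 called genes against 8.61% of tested genes, and their read assignment is uncertain. Rps13 (ENSMUSG00000090862, chromosome 7, 116331505 to 116334195), a component of the small ribosomal subunit, was lower in the knockout, 79.2 ± 20.8 against 413 ± 32.6 (-2.39 ± 0.20, limma adjusted p = 3.67e-05, n = 2 and 3). Its processed copy Rps13-ps1 was 841 and 701 in the knockout naive libraries and at most 14.9 in any wild-type library. Another copy, Rps13-ps2, was listed at 0 in all 4 knockout libraries and lay between 224 and 368 in the wild-type libraries. Tuba1c, an alpha-tubulin with near-identical copies, was 176 ± 2.19 in the knockout and 1.15 ± 0.411 in wild type (6.39 ± 0.49, limma adjusted p = 1.89e-05).

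Hddc3, a predicted metal-dependent hydrolase, was the only called protein-coding gene without such a copy. It lies 0.996 Mb from Cpeb1 (chromosome 7, 80343104 to 80350547) and was 66.0 ± 24.4 in knockout and 6.16 ± 2.92 in wild-type naive neurites (3.26 ± 0.45, limma adjusted p = 0.00651, n = 2 and 3). Of its exon bases 11.3% overlap the antisense gene Man2a2, so the source of its reads is uncertain in an unstranded library. It did not pass without knockout naive replicate 1 (limma adjusted p = 0.3), nor when only the naive libraries were used, nor when only protein-coding genes without a copy were tested, where 0 genes were called. The remaining called gene, Gm37750, an unnamed model picked after its values were seen, was listed at 0 in all 4 knockout libraries and was at least 240 in each wild-type library.

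Transcripts of immune cells were higher in the knockout naive neurites. Microglia and macrophage markers had a median of 1.58, and all 13 measured were above 0 (camera adjusted p = 1.9e-06, and adjusted p = 0.0473 with an estimated correlation), the 1 list call in any comparison that passed with an estimated correlation. None rose over all genes and 3 rose when adjusted over the list alone. Lyz2, the lysozyme of myeloid cells, was 265 ± 177 against 38.6 ± 13.3 (2.63 ± 0.76, limma adjusted p = 0.892), and Fcer1g, an immune receptor subunit, was 27.8 ± 26.5 against 1.55 ± 1.34 (3.30 ± 0.87, limma adjusted p = 0.646, n = 2 and 3). C1qb, a complement subunit, was listed at 0 in all wild-type naive libraries and was 2.80 and 11.3 in the knockout naive libraries. Inflammatory cytokines and chemokines had a median of 0.64 over 17 measured genes, of which none rose over all genes and 3 rose when adjusted over the list alone (camera adjusted p = 3.42e-06, and adjusted p = 0.127 with an estimated correlation). The chemokine Ccl4 was 2.78 and 3.78 in the knockout naive libraries and listed at 0 in the other 8 libraries, and it passed with no filter or without a trend (limma adjusted p = 0.00119 and 0.0262, against 0.274). Interferon-stimulated genes had a median of 0.84 (camera adjusted p = 1.47e-05, and adjusted p = 0.386 with an estimated correlation), with none of 23 measured passing either test. Ifitm3, an antiviral membrane protein, had a value of 1.29 ± 0.40 (limma adjusted p = 1). Without knockout naive replicate 1 the camera calls for cytokines and for interferon-stimulated genes ended (medians 0.29 and 0.87, adjusted p = 0.319 and 0.113). The cytokine median was 1.45 without wild-type naive replicate 3 and 1.19 without knockout naive replicate 2, and the interferon median was 1.44 without the latter.

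Nuclear-encoded oxidative phosphorylation genes had a median of 0.35 in knockout relative to wild-type naive neurites, and 74 of 76 were above 0 (camera adjusted p = 3.14e-18, and adjusted p = 0.386 with an estimated correlation). None passed over all genes or adjusted over the list alone, and the median was 0.22 without knockout naive replicate 1 and 0.11 with quantile normalization. Ndufv2 and Cox5b, respiratory chain subunits, had values of 0.59 ± 0.18 and 0.48 ± 0.16 (limma adjusted p = 0.987 and 1, n = 2 and 3). In this comparison limma called 23 genes, 20 higher and 3 lower, and 590 had an unadjusted p under 0.05. Without wild-type naive replicate 1 it called 16 higher and 11 lower. The number was 52 with no filter and 15 when only the naive libraries were used.

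The injured comparison of genotypes asked the same question of regrowing neurites. Penk was listed at 0 in all 3 wild-type injured libraries and was 14.3 and 13.3 in the knockout injured libraries (limma adjusted p = 0.00221). Rogdi, a gene linked to synaptic vesicles, was 76.1 ± 17.9 in knockout and 16.51 ± 4.004 in wild-type neurites (2.14 ± 0.29, limma adjusted p = 0.00516, n = 2 and 3). Cdk9, the kinase that releases RNA polymerase for elongation, was lower in the knockout, 9.43 ± 3.95 against 42.8 ± 5.90 (-2.11 ± 0.34, limma adjusted p = 0.02), as was Malat1, 1830 ± 840 against 5988 ± 579 (-1.79 ± 0.29, limma adjusted p = 0.02). Scg2, a secretory granule protein, and Kif1a, a kinesin that carries vesicles along axons, were lower by log2 values of -1.42 ± 0.26 and -1.29 ± 0.23 (limma adjusted p = 0.0417 for both).

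The groups compared differ in the share held by CT010467.1 and AY036118, 23.8% in wild-type injured and 13.6% in knockout injured libraries, so a difference in RNA quality stays open for the values of this comparison. Immediate early genes were lower as a group in injured knockout neurites, with a median of -1.24 and 1 of 30 above 0 (camera adjusted p = 1.69e-10, and adjusted p = 0.592 with an estimated correlation). None fell over all genes and 9 fell when adjusted over the list alone. The median was -0.58 without knockout injured replicate 1 and -1.89 without knockout injured replicate 2. Astrocyte markers also had a lower median in this comparison, -0.54 (camera adjusted p = 0.00583, and adjusted p = 0.735 with an estimated correlation), and that call ended without wild-type injured replicate 3 or knockout injured replicate 1 (medians -0.23 and -0.26, adjusted p = 0.293 and 0.296). Nr4a1 had a value of -2.09 ± 0.42 and Arc, a synaptic plasticity gene, one of -2.98 ± 0.67 (limma adjusted p = 0.0728 and 0.12, n = 2 and 3), and Nr4a1 passed with a pseudocount of 5 (limma adjusted p = 0.039). Genes of the integrated stress and unfolded protein responses had a median of -0.40 over 32 measured, none of which passed either test (camera adjusted p = 0.00781, and adjusted p = 0.322 with an estimated correlation). Among them Trib3 and Atf5, which act downstream of the stress kinases, had values of -2.05 ± 0.61 and -1.07 ± 0.33 (limma adjusted p = 0.268 and 0.299). Nuclear-retained transcripts had a median of -0.46 over 12 measured, of which 1, Malat1, fell, and 2 when adjusted over the list alone (camera adjusted p = 0.00583, and adjusted p = 0.592 with an estimated correlation). In naive neurites the same list was also lower in the knockout, with a median of -0.30 and 10 of 12 below 0 (camera adjusted p = 0.00451, and adjusted p = 0.386 with an estimated correlation). That call ended without knockout naive replicate 1 (median -0.10, adjusted p = 0.319), and the median was -0.47 without knockout naive replicate 2.

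The genes called between genotypes in naive neurites differed again after injury. Of these 23 calls 21 were pseudogenes or had a near-identical copy, and calls within a family are not independent. All 23 genes called in naive neurites had the same sign in injured neurites and 22 were called there too (limma's fry, adjusted p = 3.55e-09 for the higher set), among them Rps13 (-2.61 ± 0.20, limma adjusted p = 1.64e-05, n = 2 and 3), Hddc3 (2.63 ± 0.45, limma adjusted p = 0.03) and Tuba1c (3.20 ± 0.49, limma adjusted p = 0.014). Over all genes the correlation was weak (Pearson r 0.203, Spearman rho 0.0641, across genes, which are not independent replicates). Of all tested genes 50.8% had the same sign in both states. With no filter 61.5% of the naive calls had the same sign.

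In injured neurites limma called 41 genes, 27 higher and 14 lower in the knockout, of which 26 were pseudogenes or had a copy, and 1642 had an unadjusted p under 0.05. The number was 24 without knockout injured replicate 2, 15 (5 higher and 10 lower) when only the injured libraries were used and 2 when only protein-coding genes without a copy were tested. With a minimum value of 5 it was 50, 25 in each direction. Rogdi was lost without knockout injured replicate 2 (limma adjusted p = 0.126), and Cdk9 without it or wild-type injured replicate 3 (limma adjusted p = 0.194 and 0.0505). Malat1 was lost without wild-type injured replicate 1 or 2 or knockout injured replicate 1 (limma adjusted p = 0.093, 0.0522 and 0.302). Scg2 was lost without any library but knockout injured replicate 2 (limma adjusted p = 0.0606 to 0.366) and Kif1a without any but wild-type injured replicate 1 (limma adjusted p = 0.0653 to 0.274). Tuba1c was lost without either knockout injured library (limma adjusted p = 0.141 and 0.184), and Hddc3 without wild-type injured replicate 1 or 3 or any knockout library (limma adjusted p = 0.0554 to 0.247). The camera call for stress response genes ended without wild-type injured replicate 1 or knockout injured replicate 1 (adjusted p = 0.0571 and 0.114), and that for nuclear-retained transcripts without knockout injured replicate 1 (adjusted p = 0.066). In a fit of only the injured libraries Penk and Rogdi were lost (limma adjusted p = 0.184 and 0.262). Cdk9 was lost there, without a trend, with the replicate block and among protein-coding genes without a copy (limma adjusted p = 0.0593 to 0.294). Over the settings other than leaving out a library, calls were lost for Tuba1c in 3 of 11 (limma adjusted p = 0.0585 to 0.403), Malat1 in 4 of 11 (limma adjusted p = 0.0536 to 0.411), Hddc3 in 6 of 12 (limma adjusted p = 0.0792 to 0.267), Scg2 in 9 of 12 (limma adjusted p = 0.0517 to 0.346) and Kif1a in 9 of 12 (limma adjusted p = 0.053 to 0.381).

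The interaction asked whether the injury response itself differs between genotypes. Penk, which was listed at 0 in wild-type neurites after injury alone, had a limma adjusted p of 0.457. It passed with no filter and without a trend (limma adjusted p = 0.044 and 0.0499902) and did not pass with any 1 library left out (limma adjusted p = 0.151 to 0.999). Among named genes with mean expression at or above the median, Rogdi and B4galnt1, a ganglioside synthase, had the next smallest p-values for a more positive injury effect in the knockout (2.04 ± 0.42 and 1.90 ± 0.43, limma adjusted p = 0.529 and 0.595). Fos (-3.35 ± 0.74, limma adjusted p = 0.595), Cdk9 (-2.16 ± 0.49, limma adjusted p = 0.595) and Tuba1c (-3.19 ± 0.69, limma adjusted p = 0.529) had the smallest of the other direction. Immediate early genes had a median of -1.17, with none passing over all genes and 6 lower when adjusted over the list alone (camera adjusted p = 1.19e-07, and adjusted p = 0.536 with an estimated correlation). The median was -0.53 without knockout injured replicate 1 and -1.88 without knockout injured replicate 2. Among the members Arc and Nr4a1 had values of -4.42 ± 0.94 and -2.49 ± 0.60 (limma adjusted p = 0.529 and 0.661). Cytosolic ribosomal protein genes had a median of -0.59 (camera adjusted p = 7.06e-20, and adjusted p = 0.536 with an estimated correlation). Their median level was highest in wild-type injured replicate 3, the library with the largest share of CT010467.1 and AY036118 (28.2% of the total), and the difference was -0.39 without it and -0.22 with quantile normalization. Their members Rpl23 and Rps4x had values of -0.88 ± 0.30 and -0.75 ± 0.26 (limma adjusted p = 0.791 for both).

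No gene passed the interaction test. The count was 0 with limma, 979 genes had an unadjusted p under 0.05, and the count was 0 with array weights or a replicate block, 3 without a trend and 13 with no filter. It was 1 without wild-type naive replicate 2 and 2 without wild-type injured replicate 2. The median of all genes was -0.13, and quantile normalization, median-ratio scaling and the factor multiplied by the column total moved it by 0.144, 0.131 and 0.132.

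**Figure D4:**
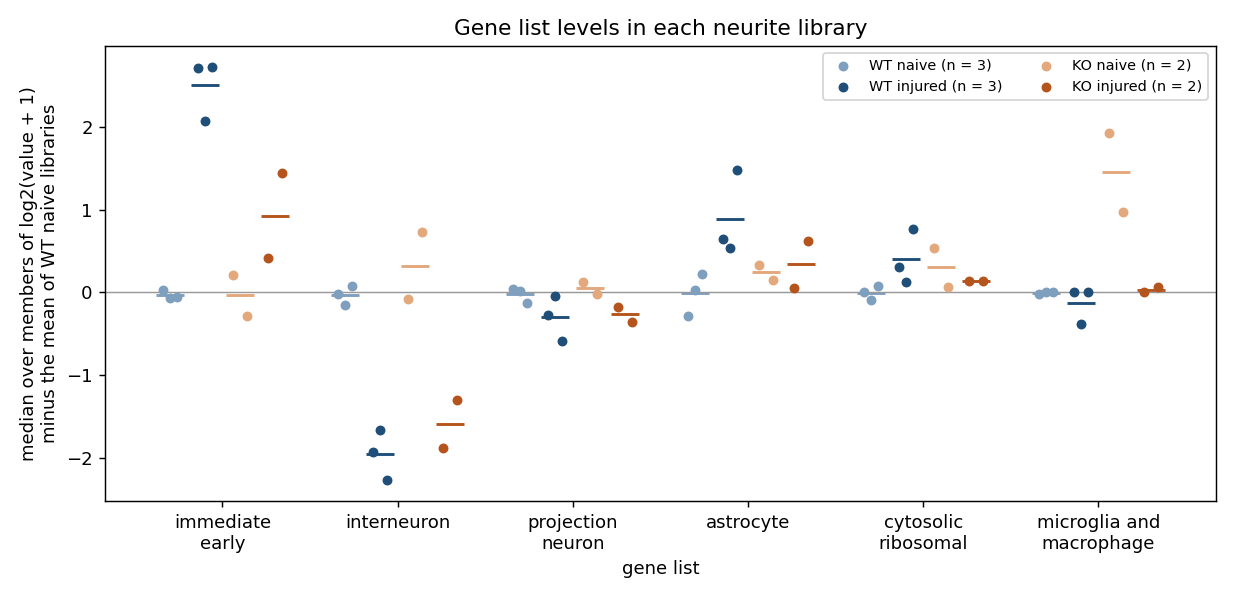
Median log2 level of 6 gene lists in each library, relative to the mean of the wild-type naive libraries, by group, where each point is 1 library and each line a group mean. Immediate early genes lie at 2.07 to 2.73 in wild-type injured and at 0.42 and 1.44 in knockout injured libraries, and interneuron markers lie at -1.30 or below in all 5 injured libraries.

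Transcripts with a cytoplasmic polyadenylation element, the motif that Cpeb1 binds, were compared with transcripts lacking it. Of 13110 tested genes with an annotated 3' untranslated region 8236 held the motif. Their median log2 fold change differed from that of the other genes by -0.05 between genotypes in naive neurites and by -0.06 in injured neurites (camera adjusted p = 0.823 for both, and adjusted p = 0.0763 and 0.116 with an estimated correlation). After injury the difference was 0.00174 in wild-type and -0.01 in knockout neurites, and in the interaction it was -0.00852 (camera adjusted p = 0.998 for all 3). With so many genes holding the motif, a preset correlation of 0.01 leaves camera little power for a small shift. The p-values with that setting therefore do not argue against one. The estimated correlation was 0.00125. The list of reported Cpeb1 targets was not called in any comparison, with medians of 0.05 and -0.13 between genotypes in naive and injured neurites (camera adjusted p = 0.81 and 0.178). In naive neurites its mean, -0.038, and the direction of its test were opposite to its median. The related genes Cpeb2, Cpeb3 and Cpeb4 did not pass any comparison. Cpeb2 had a value of 1.41 ± 0.59 after injury in wild type (limma adjusted p = 0.319, n = 3 and 3), and Cpeb3 had one of -1.39 ± 0.68 between genotypes in injured neurites (limma adjusted p = 0.5, n = 2 and 3). Over the alternatives these values ranged from 0.93 to 2.02 and from -2.32 to -0.46.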

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

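The test of nuclear-retained transcripts and the other scalings of the lists were tests chosen only after the result was seen, while the tests without wild-type injured replicate 3 were set before it. For 11 gene lists camera found an injury response that differed between genotypes, tested as the interaction, and for none of them did this pass with an estimated correlation (adjusted p = 0.445 to 0.679).

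Immediate early genes had an injury response lower in the knockout by a median log2 value of -1.17 (camera adjusted p = 1.19e-07), against a median of 2.46 after injury in wild-type and 1.06 in knockout neurites (adjusted p = 0.0892 and 0.197 with an estimated correlation). The library that stood apart, wild-type injured replicate 3, is argued against as the source of the wild-type value, since without it 12 of the 14 early genes were still called and the list's median was 2.30. Cell bodies or nuclei left in injured libraries cannot be told apart from a response within neurites: nuclear-retained transcripts had a median of -0.17 after injury in wild type and -0.32 in the knockout, but their naive level, 66.9 and 53.7 against 3.01 and 3.68 for early genes, would hide a small share of nuclei. Their only called member after wild-type injury, Malat1, rose by 1.23, and the small nuclear RNA Rn7sk, not on the list, by 4.67. The source of the Rn7sk reads is uncertain, since the libraries were primed from poly(A) tails. Between genotypes in injured libraries that list had a median of -0.46 (camera adjusted p = 0.00583) and Malat1 a value of -1.79. Both were lower in the knockout, as were early genes, and the list did not pass with an estimated correlation. A difference in the response that follows from the loss of Cpeb1 may also account for the lower value in the knockout and stays open, as untested, since genotype coincides with line and any difference in handling, and so does a difference in RNA quality, as the pair CT010467.1 and AY036118 held 23.8% in wild-type injured and 13.6% in knockout injured libraries. Knockout injured replicates differed from each other, 0.42 and 1.44 relative to wild-type naive, and the difference was -0.53 without replicate 1 and -1.88 without replicate 2.

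Cytosolic ribosomal protein genes had a median difference of -0.59 (camera adjusted p = 7.06e-20), which was -0.39 without wild-type injured replicate 3. Nuclear-encoded oxidative phosphorylation genes had one of -0.35 (camera adjusted p = 3.79e-06), which was -0.22 without wild-type injured replicate 3 and -0.23 without knockout naive replicate 1. Astrocyte markers had one of -0.70 (camera adjusted p = 0.000681), which was -0.44 without wild-type injured replicate 3.

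The other calls ended when some single libraries were left out. Translation initiation and elongation factors had a median of -0.30 (camera adjusted p = 0.0106), and the call ended without wild-type injured replicate 3 or knockout naive replicate 1 (adjusted p = 0.1 and 0.195, median -0.18 without the latter). Heat shock and proteostasis genes had one of -0.34 (camera adjusted p = 0.0106), lost without knockout injured replicate 1 (adjusted p = 0.0983). Genes of the integrated stress and unfolded protein responses had one of -0.52 (camera adjusted p = 0.0358), lost without wild-type naive replicate 1 or 2, wild-type injured replicate 1, knockout naive replicate 1 or knockout injured replicate 1 (adjusted p = 0.0571 to 0.287). Radial glia and progenitor markers had one of -0.58 (camera adjusted p = 0.0358), lost without wild-type naive replicate 1, wild-type injured replicate 1 or 3, knockout naive replicate 1 (median -0.33) or knockout injured replicate 1 (adjusted p = 0.0694 to 0.516). Cell cycle genes had one of -0.46 (camera adjusted p = 0.0292), lost without wild-type naive replicate 1, wild-type injured replicate 3, knockout naive replicate 1 or knockout injured replicate 1 (adjusted p = 0.053 to 0.694). Their median was -1.004, -1.13 and -0.77 without wild-type injured, knockout naive or knockout injured replicate 2.

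Inflammatory cytokines and chemokines had a median difference of -1.27 (camera adjusted p = 0.00612), lost without knockout naive replicate 1 or knockout injured replicate 2 (medians -0.58 and -0.71, adjusted p = 0.516 and 0.052). Microglia and macrophage markers had one of -1.10 (camera adjusted p = 0.0292), lost without wild-type naive replicate 1, wild-type injured replicate 2 or 3, knockout naive replicate 1 or knockout injured replicate 1 (adjusted p = 0.0501 to 0.331), with a median of -1.84 without knockout naive replicate 2. Relative to wild-type naive the cytokine median was 1.602 and 0.52 in the knockout naive and 0.64 and 0 in the knockout injured libraries, and the microglia median was 1.93 and 0.97 in the knockout naive libraries. Both medians were 0 or below in the wild-type injured libraries.

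Scaling was tried for all 11 lists, with quantile normalization, median-ratio scaling and the factor multiplied by the column total, given in this order. Calls ended with all 3 for translation factors (medians -0.10, -0.13 and -0.13, adjusted p = 0.143 to 0.534), heat shock genes (-0.13, -0.18 and -0.18, adjusted p = 0.12 to 0.684), stress response genes (-0.37, -0.36 and -0.36, adjusted p = 0.131 to 0.156) and radial glia markers (-0.42, -0.42 and -0.42, adjusted p = 0.0518 to 0.0978). The call for oxidative phosphorylation genes ended with quantile normalization (median 0.0027, adjusted p = 0.94) and the median was -0.18 with the other scalings. The ribosomal median was -0.22 with quantile normalization, and the cell cycle median -0.29 and -0.30 with the other scalings. The calls for ribosomal protein, cell cycle, immediate early, astrocyte, cytokine and microglia genes were kept in each.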

How the results depend on the processing

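The factor multiplied by the column total, the scalings of the lists, and the restriction to protein-coding genes without a copy, were tests chosen only after the results were seen, while the other alternatives, the lists, the tests of genes and lists and the rule for named genes were set before the data were examined. The counts of genes and lists moved most, the cause was not tested unless given, and a depth of 20.9 to 27.3 (in units of 1e6 fragments) limits genes at values near 1. Where leaving out a library left a group with 1, that library was assumed to vary like the other groups.

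Counts are given in the order wild-type injury, knockout injury, genotype in naive, genotype in injured and interaction where all moved. With an estimated correlation the lists called were 0, 0, 1, 0 and 0, and with fry and the replicate block 0 in each, against 15, 10, 7, 5 and 11, and fry without the block, which does not compare a list with other genes, called 9, 1, 1, 0 and 0. With no filter 25, 33 and 52 genes were called in the first 3 and 13 in the interaction, and 61.5% of naive genotype calls kept their sign in injured neurites. Without trend the counts were 77, 1 and, in the interaction, 3. A fit of only the groups compared gave 17, 0, 15 and 15, with fewer libraries to estimate the spread. The spread was also unequal, with array weights of 0.774, 0.7598 and 0.405 in wild-type injured libraries and at least 0.956 in every other library. A spread pooled over all groups may therefore be too small for comparisons that use wild-type injured libraries. With array weights 109 genes were called for wild-type injury and 28 for genotype in injured neurites, against 149 and 41. What lowered the counts was not tested. The replicate block gave 73 and 3 for the injury comparisons, and deviations from the group mean in libraries sharing a number correlated by -0.0484 to 0.0409. Knockout injury counts were 4 with quantile normalization, 20 with array weights, 1 with a pseudocount of 0.1 and 14 with the factor multiplied by the column total. Protein-coding genes without a copy gave 0 for genotype in naive and 2 in injured neurites, where fewer genes were tested and the copies were removed.

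Leaving out each library gave 35 to 311, 0 to 20, 17 to 27, 24 to 57 and 0 to 2 genes, and 11 to 16, 5 to 13, 3 to 9, 2 to 9 and 5 to 12 lists. The share of wild-type injury calls with the same sign in the knockout was 70.1% to 88.7%, and that of naive genotype calls in injured neurites 94.1% to 100%. Of 41 calls of named genes 41 were kept with a minimum value of 5, 40 with a pseudocount of 5, 37 with median-ratio scaling or the multiplied factor, 34 with quantile normalization, 30 with array weights or a pseudocount of 0.1, 27 with the replicate block, 21 without trend, 16 with no filter and 12 in a fit of only the groups compared. With 1 library left out 22 to 34 were kept.

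Directions reversed for small values. Nuclear-retained transcripts after wild-type injury had a median of -0.17 with the replicate block, where fry gave a direction opposite to camera's, and -0.28 to 0.018 with a library left out. Cpeb1 after knockout injury was 0.14 with quantile normalization, 0.017 with median-ratio scaling, 0.27 with a pseudocount of 0.1 and 0.00149 with the factor multiplied by the column total. Cpeb3 between naive genotypes was -0.035 with quantile normalization, -0.043 with median-ratio scaling, -0.044 with the multiplied factor, -0.0055 with array weights and -0.074 with the replicate block. Cpeb4 there was -0.00314 with median-ratio scaling, -0.28 with the block and -0.00217 with the multiplied factor. With a library left out, Cpeb1 ranged from -1.23 to 1.13 after knockout injury, -0.22 to 1.35 after wild-type injury and -1.64 to 0.72 in the interaction. Cpeb2 between naive genotypes ranged from -0.41 to 0.039, Cpeb3 from -0.42 to 0.43 there and -1.29 to 0.56 after knockout injury, and Cpeb4 from -0.48 to 0.59 between naive genotypes, -0.75 to 0.32 after knockout injury and -0.22 to 0.85 in the interaction. The motif difference was 0.00236 in the interaction with the shorter motif alone, and 0.0566 after knockout injury adjusted for length and GC content. The latter is an adjusted difference of means set against a difference of medians of -0.01. The direction of the test was up both with and without that adjustment, so it did not reverse.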

Other observations

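The test of distance from Cpeb1, the other scalings of the lists and the choice of genes and shares named here were made only after the result was seen. After injury of wild-type neurites, further lists were called beside those of the report. Cell cycle genes had a median of 0.91 with 27 of 31 above 0 (camera adjusted p = 2.24e-05, and adjusted p = 0.341 with an estimated correlation; median 0.55 without wild-type injured replicate 3), none passing over all genes and 1, the mitotic kinase Cdk1 (1.66 ± 0.37, limma adjusted p = 0.0553, n = 3 and 3), when adjusted over the list alone. Targets of p53 had a median of 0.55 (camera adjusted p = 0.0117, and adjusted p = 0.283 with an estimated correlation), and 1 of 24, the cell cycle inhibitor Cdkn1a, rose (1.73 ± 0.29, limma adjusted p = 0.0154), and 2 when adjusted over the list alone. Growth cone and guidance genes had a median of -0.28 (camera adjusted p = 0.0113, and adjusted p = 0.341 with an estimated correlation), with 1 of 46, the actin regulator Pfn2, falling (-0.69 ± 0.15, limma adjusted p = 0.0478), and 1 rising and 4 falling when adjusted over the list alone. Without wild-type injured replicate 3 the calls for p53 targets and growth cone genes ended (medians 0.30 and -0.081, adjusted p = 0.125 and 0.122). Leaving out libraries was not run for Cdk1, Cdkn1a and Pfn2. Dendritic mRNAs had a median of -0.32 (camera adjusted p = 0.00341, and adjusted p = 0.194 with an estimated correlation), cholesterol synthesis genes one of -0.25 (camera adjusted p = 0.00543, and adjusted p = 0.194 with an estimated correlation) and translation factors one of 0.19 (camera adjusted p = 0.0117, and adjusted p = 0.449 with an estimated correlation). The dendritic median was -0.17 without wild-type naive replicate 3, and the call for translation factors ended without wild-type naive replicate 2 or wild-type injured replicate 3 (adjusted p = 0.0602 and 0.16, median 0.12 without the latter). It also ended with quantile normalization, median-ratio scaling and the factor multiplied by the column total (medians 0.058, 0.12 and 0.083, adjusted p = 0.0516 to 0.351), and the cholesterol median was -0.38 with quantile normalization.

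In knockout neurites, presynaptic genes had a median of -0.28 after injury (camera adjusted p = 0.00422, and adjusted p = 0.415 with an estimated correlation), microtubule and neurofilament genes one of -0.20 (camera adjusted p = 0.0145, and adjusted p = 0.197 with an estimated correlation), and inflammatory genes one of -0.86 (camera adjusted p = 0.0298, and adjusted p = 0.415 with an estimated correlation). The presynaptic call ended without knockout naive or knockout injured replicate 2 (adjusted p = 0.0636 and 0.277), and the median was -0.46 without knockout injured replicate 1. The microtubule call ended with quantile normalization, median-ratio scaling and the factor multiplied by the column total (medians 0.00018, -0.11 and -0.14, adjusted p = 0.0665 to 0.571), and the presynaptic median was -0.18 with median-ratio scaling. The microtubule call also ended without knockout naive replicate 1 or knockout injured replicate 2 (adjusted p = 0.104 and 0.135). The inflammatory call ended without wild-type injured replicate 3, knockout naive replicate 1 or knockout injured replicate 2 (medians -0.86, 0.0054 and -0.56, adjusted p = 0.0538, 0.837 and 0.356), and the median was -1.30 without knockout naive replicate 2. Cytosolic ribosomal protein genes had a median of 0.29 between genotypes in naive neurites and -0.27 in injured neurites (camera adjusted p = 7.94e-13 and 6.05e-08, and adjusted p = 0.84 and 0.793 with an estimated correlation). The naive call ended without knockout naive replicate 1 (median 0.068, adjusted p = 0.565) and the median was 0.54 without replicate 2, and the injured call ended without wild-type injured replicate 3 (median -0.081, adjusted p = 0.156). With quantile normalization the naive call ended (median 0.025, adjusted p = 0.38), and the injured median was -0.16, -0.18 and -0.18 with quantile normalization, median-ratio scaling and the multiplied factor.

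Pseudogenes and gene copies made up 21 of 23 genotype calls in naive and 26 of 41 in injured neurites. That such genes were carried along with the floxed allele is argued against by position, since 3.70% of the called pseudogenes and copies, 1 of 27, lay within 20 Mb of Cpeb1. This holds only where reads were assigned to the right copy, which is uncertain. Calls within a family are also not independent, and Rps13-ps2 shares a family with Rps13 and Rps13-ps1, which lie outside that window. Of all 42 genes called in either state 2 lay within 20 Mb of Cpeb1, Hddc3 and Rps13-ps2, against 1.37% of tested genes (Fisher's exact test, one-sided p = 0.113), so linkage stays open for that pair. Sequence variants of the floxed line that move reads between near-identical copies may account for the pattern, but the medians could hardly have come out otherwise: family sums differed by a median absolute log2 ratio of at most 0.359 while single members differed by 5.95 and 4.62, and sums would lie near 0.25 and 0.26 even with the other copies unchanged. Single families tell more. The sum over Rps13 and its copies differed by -0.27 in naive and -0.76 in injured neurites, against -1.46 and -1.67 if only Rps13 changed. The copies together differed by 1.67 and 1.33, opposite to Rps13. In injured neurites the Gm47283 sum, -1.41, stayed near the -1.58 given by unchanged copies. The Kpna2 sum was 0.64 against -1.38, its copy at 6.08 and Kpna2 at -1.41 (limma adjusted p = 0.0417, lost in 7 of 11 settings). Whether genotypes were sequenced and quantified together is not given and stays open, untested, as does an effect of Cpeb1 loss.

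Interneuron markers had medians of -1.74 and -1.96 after injury in wild type and knockout, called by camera and not with an estimated correlation (adjusted p = 0.0623 and 0.0608). The gap between interneuron and projection neuron medians was -1.28 in wild type and -1.65 in the knockout. It cannot tell if a lower yield of neuronal RNA was the only source, as the cellular origin of projection neuron markers was not tested. The projection neuron medians were -0.46 and -0.31, with members in both directions in wild type. Camera also called presynaptic and dendritic lists lower in both genotypes. Such a yield, fewer regrown interneuron neurites and less of these transcripts in them all stay open, as untested.

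Of the 10 ways to split the 6 wild-type libraries into groups of 3, the real one called 149 genes and the highest of the others 2, and 1 of 10 gave as many as the real one. The 10 splits are too few for a share under 0.05.

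The annotation lists CT010467.1 as ribosomal RNA, and AY036118, listed as a long noncoding RNA, lies within it on the same strand. The pair held 14.1% ± 2.71 (SD, n = 3) of the total in wild-type naive, 23.8% ± 4.21 (SD, n = 3) in wild-type injured, 14.8% ± 3.03 (SD, n = 2) in knockout naive and 13.6% ± 2.16 (SD, n = 2) in knockout injured libraries. It was 19.9%, 23.3% and 28.2% in wild-type injured replicates 1, 2 and 3, and replicate 3 also had the highest levels of ribosomal protein, astrocyte, radial glia and cell cycle lists. The higher share lies in the wild-type injured group, which enters the wild-type injury, injured genotype and interaction values, so a difference in RNA quality or in the carry-over of ribosomal RNA stays open for those list values, as untested.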
